A study of Mus musculus with 12 samples.

How the data were processed

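Small RNA was sequenced from the hippocampus of 12 male C57BL/6J wild-type mice, 6 in the exercised lineage and 6 in the sedentary lineage. The labels number the mice 1 to 6 in each group, so each library came from its own animal, and each was placed in its group by its title. Per the labels' protocols, RNA was extracted with an miRNeasy kit and libraries were made with the NEBNext small RNA kit, and the labels name no molecular identifiers. PCR copies were therefore not told apart from separate molecules.

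The deposited values are a non-negative signal, namely reads per mature miRNA arm divided by 1 size factor per library. Per the submitters' processing notes, Bowtie 1.3.0, the mouse build mm10 and DESeq2 were used. Adapter trimming, allowed mismatches, the treatment of reads that match several loci and the filter on rows are not given in the sources used here. The column names call the values raw, yet they are not whole. In every library 100% of the values are whole multiples, within 0.01, of 1 step that differs between libraries, and the median-of-ratios factor recomputed from the deposited values was 1.004 in all 12. With the step taken as 1 read, depth was 6862623 to 10219856 reads per library. The smallest positive value in a library stood for 2 to 6 reads, so the step could not be read from the smallest value itself. For that reason no count model was fitted, although the recovered reads would have allowed one. The step and the recovered reads served for depth, the reads expected at values of 0, the simulations and the comparison of library pairs. Arms with identical sequence share a row, so near-identical paralogues cannot be separated.

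Values of 0 were looked at separately. Among the 5688 values of the tested arms, 63 were 0. In 56 of these, the mean of the other 11 libraries corresponded to 10 or more reads, with a highest expectation of 86.5 reads. Counting noise alone (Poisson) would give 0.0022 such values. They lay in 31 arms, 17 of them passenger arms, with 27 in exercised-lineage and 29 in sedentary-lineage libraries. A value of 0 is therefore given as listed at 0.

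Differences between the groups were tested in R 4.3.3 with limma 3.58.1 (linear model, empirical Bayes with a mean-variance trend) on log2(value + 1). This was the choice fixed beforehand for values that are not whole reads. Arms with a mean of at least 10 over the 12 libraries entered the test, which kept 474 of 513. The fold is the exercised minus the sedentary lineage on that scale, which understates differences of low values. A call needed a Benjamini-Hochberg adjusted p below 0.05. Values per library were compared with exact permutation tests over all 924 assignments, two-sided.

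Row names follow MirGeneDB, which names an arm by family, paralogue (P) and strand and marks the passenger arm with an asterisk. The 22 lists of miRNAs were fixed before the data were examined, by miRBase number. They were matched to the rows by family or paralogue before any group difference was computed. Some fixed members gained no row, such as let-7b in the neurogenesis list, miR-188 in the plasticity list and miR-29c in the paternal stress list. Some family rows beyond the fixed letter entered, such as both Mir-146 paralogues for miR-146a. List results therefore cover the matched rows only. Of the 22 lists, 19 with 3 or more tested arms were tested with camera from limma (preset correlation 0.01, two-sided). Beside it ran camera with an estimated correlation and fry. Lists overlap, so their results are not independent.

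The rule for named miRNAs was also fixed before the data were examined. It takes the called arms with the largest differences (up to 12 each way) and, if fewer than 10 pass, the 10 with the smallest p. It adds the 5 most abundant arms, up to 4 of the most abundant arms of each list, any member called over its list alone, and every arm of miR-144, miR-298, miR-132 and miR-212. It gave 84 arms. Coordinates come from the GENCODE annotation of mm10, matched by gene symbol.

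The test was run on simulated libraries with the real means and spread of these 474 arms, 6 against 6. In 5 sets with 40 changed arms each, it recovered 18% of arms changed 1.25-fold, 64% at 1.5-fold, 80% at 2-fold and 92% at 3-fold. Of 134 calls, 7 were false (5.22%), and 5 sets with no change gave 0 calls. A list of 10 arms planted at 1.5-fold was called in 20 of 20 simulations, while 4 of 380 other lists were called. Arms were drawn there independently, while members of real lists vary together (estimated correlation up to 0.79, Mir-200 and Mir-183 families). In 100 drawn splits of the real libraries, up to 6 lists were called. Arms at an unadjusted p below 0.05 numbered 4 to 70, against 19 to 26 in simulated sets with no change. The simulated rates therefore need not hold for the real libraries. For the real comparison, the 95% confidence interval reached a median of 0.34 log2 to each side, a 1.27-fold difference.

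Alternatives covered scaling, filters, pseudocounts, the mouse number as a block, the submitters' code stem, each library or stem left out, and other list tests. After the data had been seen, a choroid plexus covariate, a permutation test of list medians and a fit without the 56 values of 0 were added. None of the 66 pairs of libraries matched within counting noise (chi-square per degree of freedom 73.1 to 1216).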

Results

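Small RNA libraries were made from the hippocampus of 12 male C57BL/6J mice, a standard inbred strain, to ask whether exercise of a grandfather is associated with the miRNA profile of his grandsons. In the exercised lineage, 6 mice descended through the male line from grandfathers that had exercised. In the sedentary lineage, 6 mice descended from sedentary grandfathers. The labels describe exercise of the grandfathers only. Libraries held 6862623 to 10219856 reads on 513 miRNA arms, with 8296923 ± 1299072 in the exercised and 8587985 ± 1216807 in the sedentary lineage (SD, n = 6 each, exact permutation p = 0.697). Values are normalized counts, the reads of an arm divided by 1 size factor per library. Folds are log2 differences, exercised minus sedentary lineage. A left-out range gives the lowest and highest value with each library left out in turn. Submitter codes group the libraries into 4 sets of 3 by a shared stem, R31 and R41 in the exercised and S11 and S41 in the sedentary lineage, and the labels do not say what the stem stands for. If libraries with a shared stem are related, the 6 libraries of a lineage are not independent. Intervals and p-values that count 6 per lineage could then be too small.

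The hippocampal profile of both lineages was led by brain miRNAs. The 5p arm shared by the 3 Mir-9 genes, which are expressed in the nervous system and act in neurogenesis, stood at 2056520 ± 447264 normalized counts in the exercised and 2131170 ± 167829 in the sedentary lineage (SD, n = 6 each), and its share of all counts differed by 0.226 percentage points (exact permutation p = 0.866). Its genes lie on chromosome 3 (88215598 to 88215686), chromosome 13 (83738814 to 83738885) and chromosome 7 (79505264 to 79505353) of mm10, each in a long noncoding RNA gene. The neuronal Mir-128 3p arm, from introns of R3hdm1 and Arpp21, followed with 500812 ± 60959 against 570760 ± 108226 normalized counts. Mir-218 5p, from introns of Slit2 and Slit3, stood at 404480 ± 68972 against 403811 ± 62645. Mir-143_3p, known from smooth muscle and mural cells, stood at 364821 ± 160754 against 389280 ± 139242, and Mir-10-P2b_5p at 333759 ± 41214 against 374391 ± 42939. The folds of these 5 arms lay between -0.18 and 0.00, with limma adjusted p from 0.532 to 0.998, and between -0.28 and 0.07 with any 1 library left out. The fold of Mir-9 was -0.08, 0.04 without F2_exercised replicate 1, and 0.01 when libraries were scaled by their totals. The 10 most abundant arms together held 59.7% ± 2.00 and 60.1% ± 1.58 of the counts (exact permutation p = 0.699).

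No miRNA arm met the adjusted threshold between the lineages. The arm with the smallest p, Mir-184_3p, a regulator of neural stem cell proliferation, had 116 ± 21.5 normalized counts in the exercised and 173 ± 36.8 in the sedentary lineage (SD, n = 6 each), a fold of -0.57 (SE 0.17), with 6 of 6 exercised-lineage libraries below the sedentary median. Its gene is intergenic on chromosome 9 (89802260 to 89802328, minus strand). Among 474 arms tested with limma, 0 were called higher and 0 lower, and the lowest adjusted p was 0.532. At an unadjusted p below 0.05 there were 34 arms, 17 with a fold above 0 and 17 below, where 23.7 are expected with no difference. The 95% confidence interval lay within a 1.5-fold difference in either direction for 279 arms (58.9%) and within 2-fold for 82.7%. The number at an unadjusted p below 0.05 was 57 under upper-quartile scaling (52 above 0 and 5 below), 31 under scaling by totals (23 above and 8 below), 16 and 19 without the S11 or the S41 libraries, and 18 without F2_exercised replicate 6.

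**Figure D1:**
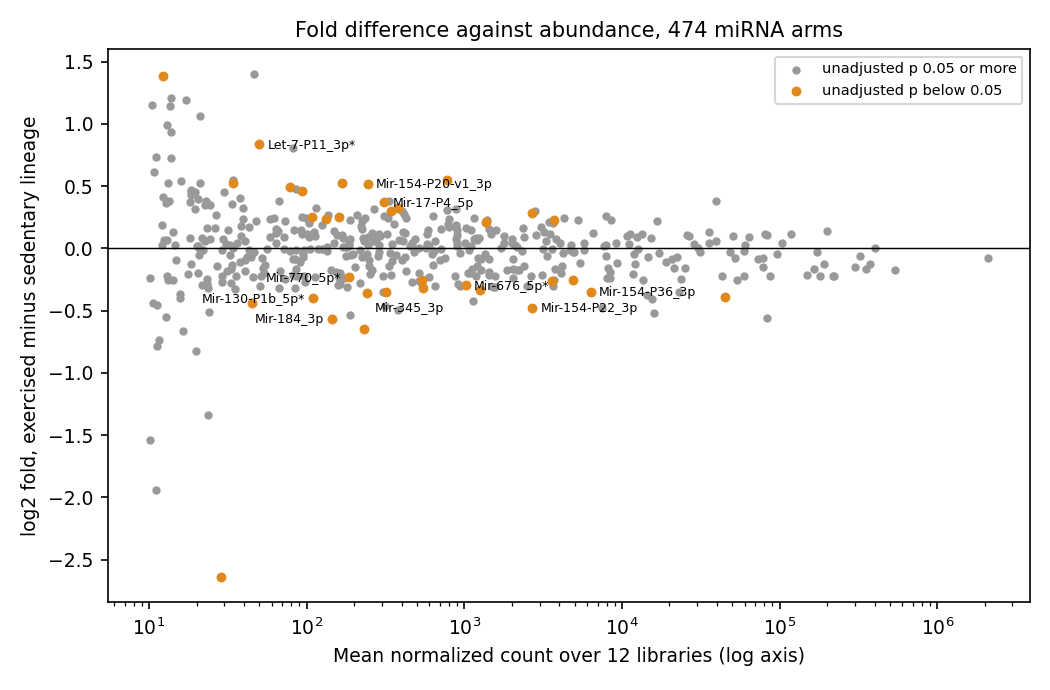
Log2 fold, exercised minus sedentary lineage (vertical axis), against the mean normalized count over 12 libraries (horizontal log axis) for 474 miRNA arms, 1 point per arm. Orange points are the 34 arms with an unadjusted limma p below 0.05, of which 0 passed adjustment, and the 10 arms with the smallest p are named.

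All 10 arms with the smallest p missed the adjusted threshold (limma adjusted p = 0.532 for each). Several belong to the imprinted Dlk1-Dio3 region of chromosome 12, which encodes a large brain-expressed miRNA cluster. Mir-154-P22_3p stood at 2251 ± 502 against 3116 ± 550 normalized counts (fold -0.48, SE 0.16), and Mir-154-P36_3p at 5571 ± 792 against 7122 ± 1174 (fold -0.35, SE 0.13). Mir-770_5p*, whose gene lies in an exon of the maternally expressed Meg3 (chromosome 12, 109563692 to 109563785), stood at 171 ± 14.5 against 201 ± 16.9 (fold -0.23, SE 0.09). In the other direction, Mir-154-P20-v1_3p had 290 ± 87.3 against 197 ± 41.9 (fold 0.52, SE 0.20). Outside the cluster, Mir-676_5p*, from an intron of Eda on chromosome X (100381097 to 100381185), had a fold of -0.30 (SE 0.11). Mir-345_3p, from chromosome 12 (108836973 to 108837068) within Slc25a47, had -0.36 (SE 0.13), and Mir-130-P1b_5p* had -0.40 (SE 0.15). Folds above 0 were found for Mir-17-P4_5p, of the growth-associated Mir-17 family, with 349 ± 60.4 against 270 ± 49.5 (0.37, SE 0.14), and for the passenger arm Let-7-P11_3p* with 64.1 ± 27.6 against 35.7 ± 13.2 (0.84, SE 0.32). The group values overlapped for all 474 arms.

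**Figure D2:**
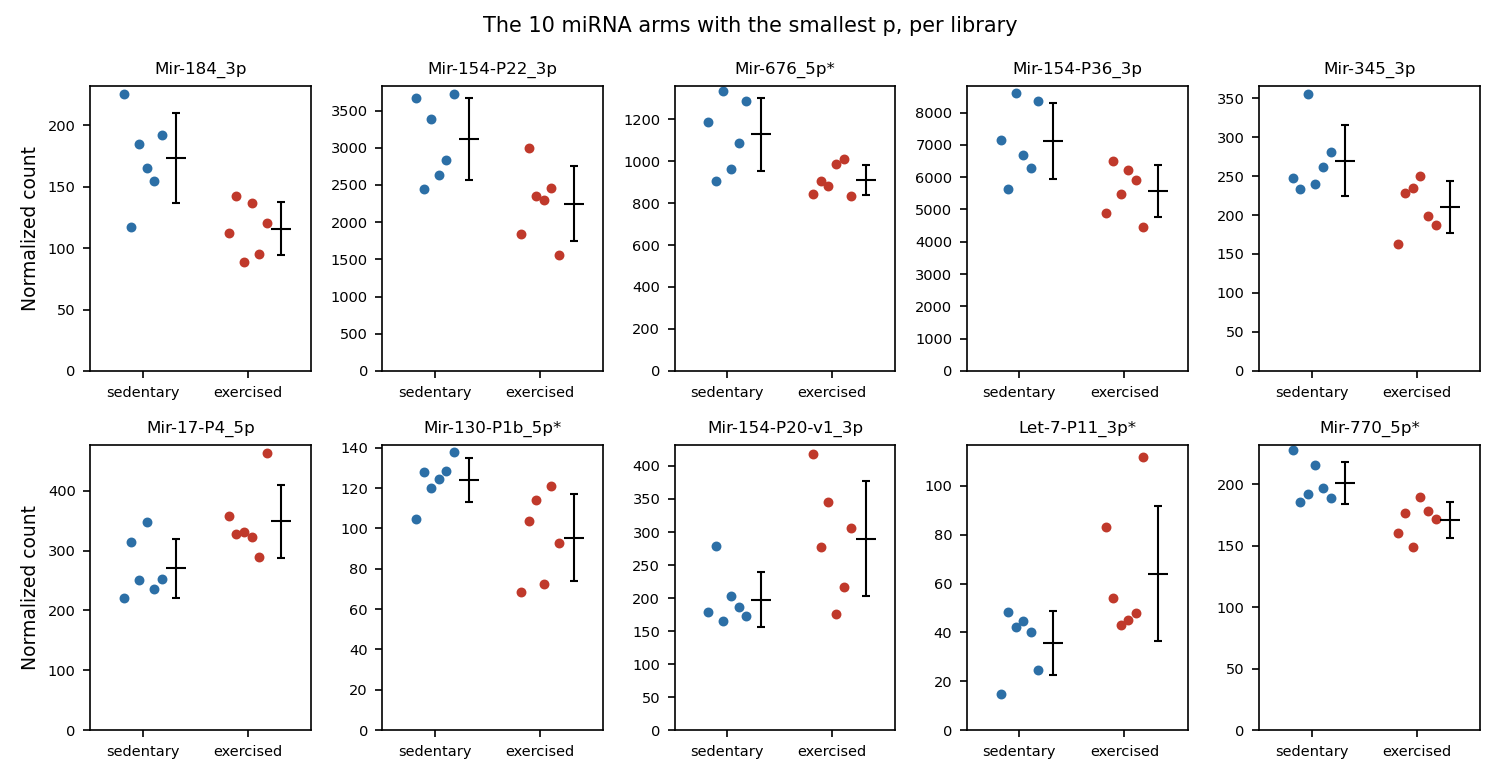
Normalized counts (vertical axis, from 0) of the 10 miRNA arms with the smallest p in each library of the sedentary (blue) and exercised (red) lineage, with mean and SD of 6 libraries as black bars. Mir-184_3p averages 116 in the exercised and 173 in the sedentary lineage, and the groups overlap in every panel.

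The arms of Mir-132, Mir-212, Mir-298 and Mir-144, chosen in advance, also did not pass. Mir-132 and its neighbour Mir-212 (Mir-132-P1 and Mir-132-P2), transcribed in neurons in response to activity, lie side by side on chromosome 11 (75173682 to 75173747 and 75173388 to 75173478). Mir-132-P1_3p stood at 13655 ± 1910 against 13043 ± 4578 normalized counts (fold 0.12, 95% confidence interval -0.27 to 0.51, but 0.28 without F2_sedentary replicate 3 and 0.04 without F2_sedentary replicate 2) and Mir-132-P1_5p at 11628 ± 706 against 10777 ± 1530 (fold 0.12, -0.09 to 0.32, left-out range 0.07 to 0.19). For Mir-212 the arms pointed apart, with 0.26 (-0.04 to 0.55) for Mir-132-P2_3p and -0.30 (-0.65 to 0.05) for Mir-132-P2_5p. Mir-298_5p, from the imprinted Gnas region of chromosome 2 (174267504 to 174267585), stood at 281 ± 65.4 against 353 ± 45.8 (fold -0.35, -0.66 to -0.04, limma adjusted p = 0.532), with F2_exercised replicate 1 at 402. The erythroid Mir-144 (chromosome 11, 78073005 to 78073070) was near the lower end of the range, with 25.5 ± 15.5 against 32.5 ± 21.1 for the 3p arm (fold -0.27, but from -0.61 without F2_sedentary replicate 3 to 0.02 without F2_exercised replicate 5) and 7.31 ± 1.52 against 15.0 ± 9.08 for the 5p arm (fold -0.79, -1.62 to 0.04).

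No list of neuronal miRNAs was called between the lineages. The neuron-enriched list held 44.0% ± 1.65 of normalized counts in the exercised and 43.8% ± 1.63 in the sedentary lineage. Of its 38 tested arms, 24 had a fold above 0 and 14 below, with 0 called over all arms or adjusted over the list alone (median 0.08, left-out range 0.04 to 0.09, camera adjusted p = 0.492). Its arm with the highest fold, Mir-124 3p, the neuronal identity miRNA, stood at 44838 ± 14706 against 33933 ± 8085 (fold 0.38, 95% confidence interval -0.05 to 0.80), with F2_exercised replicate 1 at 72090 and a fold of 0.23 without it. Mir-127_3p, from the Dlk1-Dio3 region, had a fold of -0.06 (left-out range -0.11 to -0.02), and 0.03 under scaling by totals. The list for activity and synaptic plasticity had 14 of 23 arms above 0 (median 0.11, left-out range 0.04 to 0.13, camera adjusted p = 0.692). In it, Mir-191 5p had a fold of -0.16 and Mir-146-P2_5p of -0.37 (-0.82 to 0.08), which were -0.07 and -0.19 without F2_exercised replicate 1. The list for adult hippocampal neurogenesis had 20 of 34 arms above 0 (median 0.07, left-out range 0.01 to 0.11, camera adjusted p = 0.664), with 4 at an unadjusted p below 0.05, Mir-184_3p among them. In both lists 0 arms were called over all arms or adjusted over the list alone. The list of sperm miRNAs reported after paternal stress had 7 of 15 arms above 0 and 0 calls by either count (median -0.00, left-out range -0.09 to 0.07, mean -0.01, camera direction up, adjusted p = 0.982). It covers no arm for miR-29c, miR-30a, miR-30c or miR-200b, which the list as fixed names, so it does not test the reported set as a whole. Of its arms, Mir-375_3p had a fold of -0.22 and Mir-32_5p of 0.24, which were -0.13 and 0.16 without F2_sedentary replicate 1.

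**Figure D3:**
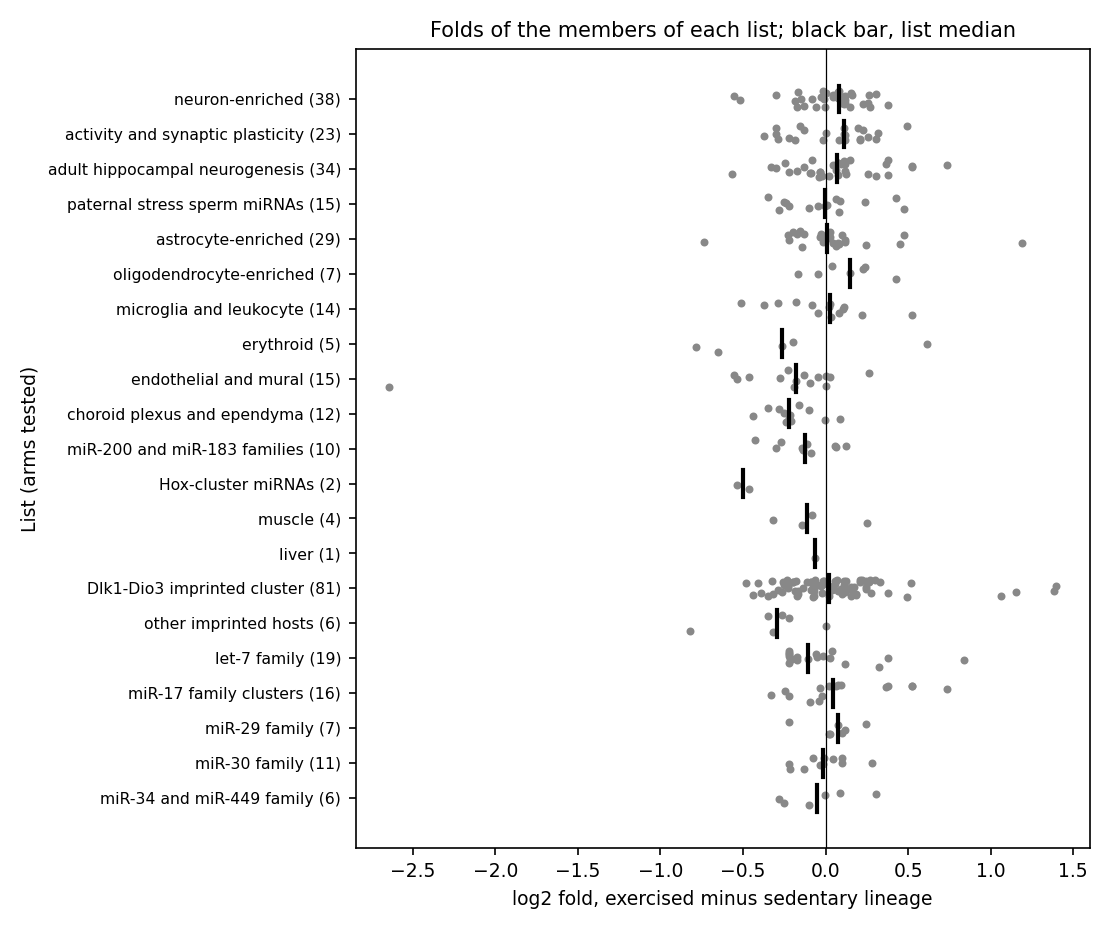
Log2 fold, exercised minus sedentary lineage (horizontal axis), of each tested arm (grey points, scattered vertically for legibility) in each list, with the number of arms in brackets and the list median as a black bar. List medians lie between -0.50 (Hox-cluster miRNAs, 2 arms) and 0.15 (oligodendrocyte-enriched, 7 arms, but -0.02 without F2_sedentary replicate 1), and no list was called.

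Markers of glia, vessels and blood were also without a called arm, over all arms or adjusted over the list alone. The erythroid list had 4 of 5 arms below 0 (median -0.27, left-out range -0.59 to -0.18, camera adjusted p = 0.418, and 0.573 with an estimated correlation). Mir-451_5p, a red cell miRNA beside Mir-144 on chromosome 11 (78073170 to 78073241), stood at 173 ± 43.6 against 286 ± 139.1 (fold -0.65, SE 0.26), with F2_sedentary replicate 2 at 550, and Mir-486_5p, from an intron of Ank1, at 479 ± 61.3 against 550 ± 69.8. The median of the erythroid list per library differed by -0.64 between the lineages (exact permutation p = 0.00649, 0.123 adjusted over 19 lists), and that of the neuron-enriched list by 0.05 (exact permutation p = 0.0130, adjusted 0.123). Of astrocyte-enriched arms, 16 of 29 were above 0 (median 0.01, left-out range -0.01 to 0.03, camera adjusted p = 0.945), with Mir-21_5p at 172726 ± 46888 against 171081 ± 28152 and Mir-26 5p at a fold of -0.15 (-0.10 without F2_exercised replicate 1 or F2_sedentary replicate 6). Of oligodendrocyte-enriched arms, 5 of 7 were above 0 (median 0.15, left-out range -0.02 to 0.24, the lowest without F2_sedentary replicate 1, camera adjusted p = 0.538), with Mir-219-P2_3p* at 11676 ± 1577 against 12318 ± 3051 and Mir-338-P1_3p at 1655 ± 280 against 1514 ± 355. The microglia and leukocyte list had 8 of 14 arms above 0, a median of 0.02 (left-out range -0.07 to 0.07), a mean of -0.03 and the camera direction down (adjusted p = 0.945). In it, Mir-150_5p stood at 1330 ± 235 against 1372 ± 216 and Mir-342_3p at a fold of 0.11 (-0.05 without F2_exercised replicate 6 and 0.28 without F2_exercised replicate 1). In the endothelial and mural list, 11 of 15 arms were below 0 (median -0.18, left-out range -0.28 to -0.05, camera adjusted p = 0.452), with Mir-126 3p, an endothelial miRNA, at 95058 ± 14205 against 97490 ± 7738 and Mir-139_5p at a fold of 0.00 (left-out range -0.03 to 0.07). Its lowest fold, -2.64, belongs to Mir-214_5p*, listed at 0 in F2_exercised replicates 1, 2 and 4 and between 24.6 and 45.3 in the other libraries, an arm chosen after its values were seen. Without the R41 libraries, this list was called (median -0.33, camera adjusted p = 0.00595, but adjusted p = 0.764 with an estimated correlation).

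No list of epithelial miRNAs was called between the lineages. The choroid plexus and ependyma list had 11 of 12 arms below 0 and 0 called over all arms or adjusted over the list alone (median -0.22, left-out range -0.47 to 0.00, camera adjusted p = 0.492, and 0.988 with an estimated correlation). Mir-1298_5p, from an intron of the serotonin receptor gene Htr2c on chromosome X (147064905 to 147065002), stood at 55376 ± 51783 against 64144 ± 49708 normalized counts. Mir-204-P1_5p, from an intron of Trpm3 on chromosome 19 (22750605 to 22750672), stood at 20227 ± 8600 against 25457 ± 8488, and Mir-34-P2b_5p, of the family active in ciliated cells, at 21449 ± 9313 against 26055 ± 12052. The list median spanned 3.52-fold over the 12 libraries. Of the Mir-200 and Mir-183 families, found in epithelia and sensory cells, 7 of 10 arms were below 0 with 0 called by either count (median -0.12, left-out range -0.27 to 0.44, camera adjusted p = 0.945). Mir-8-P1a_3p, a member of the Mir-200 family, stood at 2587 ± 644 against 4003 ± 5420, with F2_sedentary replicate 5 at 14946. Without that library the list was called with a median of 0.44 (camera adjusted p = 0.0350, but adjusted p = 0.778 with an estimated correlation). Without the R31 or the S41 libraries, the choroid plexus list was called with medians of -0.69 and -0.61 (camera adjusted p = 0.000434 and 0.00400, but adjusted p = 0.482 and 0.741 with an estimated correlation).

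**Figure D4:**
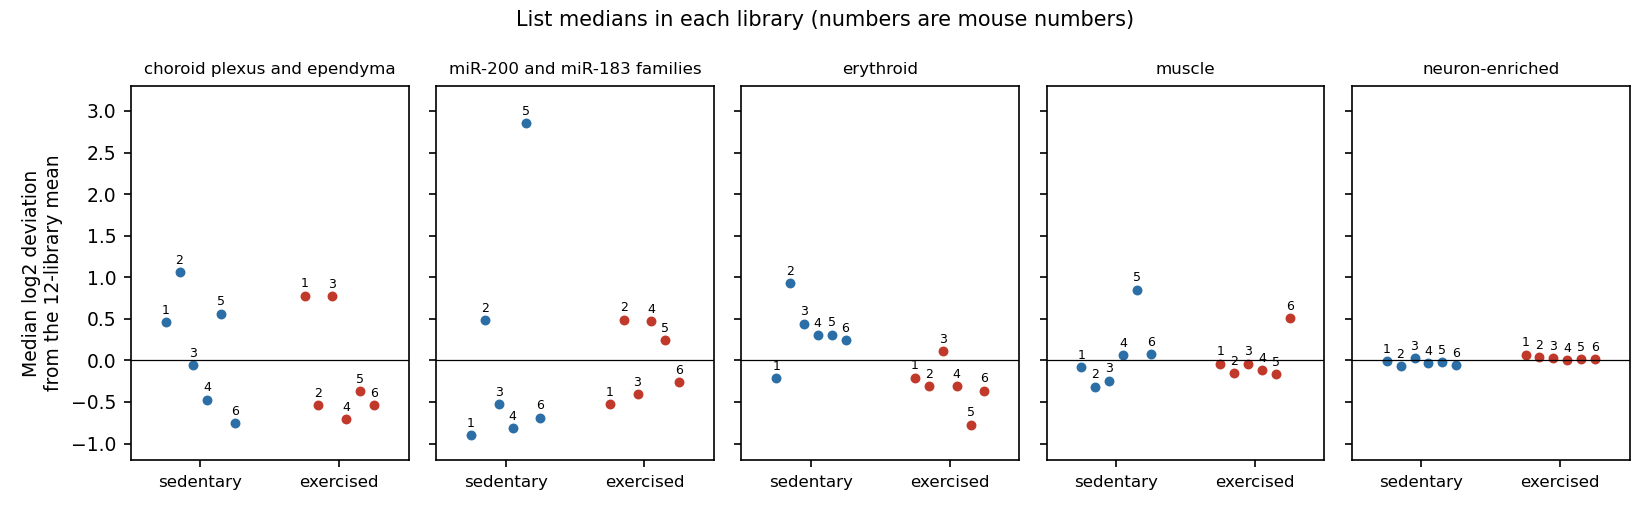
Median log2 deviation of a list's arms from the 12-library mean (vertical axis) in each library of the sedentary (blue) and exercised (red) lineage, labelled by mouse number, for 5 lists. The choroid plexus list spans 3.52-fold between libraries, the Mir-200 and Mir-183 list stands at 2.86 in F2_sedentary replicate 5, and the neuron-enriched list spans 1.10-fold.

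MiRNAs of muscle, liver and Hox clusters were also detected. In the muscle list 3 of 4 arms were below 0, with 0 called by either count (median -0.11, left-out range -0.26 to 0.05, mean -0.07, camera direction up, adjusted p = 0.982). Mir-1 3p, the heart and skeletal muscle miRNA, stood at 3915 ± 900 against 4418 ± 1508 and Mir-499_5p at 175 ± 18.3 against 147.3 ± 20.8. The liver miRNA Mir-122_5p stood at 194 ± 156 against 160 ± 45.8, a fold of -0.06 (-0.35 without F2_exercised replicate 3 and 0.18 without F2_exercised replicate 6). Both tested Hox-cluster arms were below 0, with folds of -0.46 for Mir-10-P1a 5p and -0.53 for Mir-10-P1b 5p (limma adjusted p = 0.669 and 0.685). With 1 library left out, the fold of Mir-10-P1a ran from -0.81 (F2_exercised replicate 4) to -0.20 (F2_exercised replicate 1) and that of Mir-10-P1b from -0.85 (F2_exercised replicate 4) to -0.04 (F2_exercised replicate 2). The liver and Hox lists were too small for a list test. No row of the table matched the Sfmbt2 cluster list.

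Arms of the imprinted Dlk1-Dio3 cluster lay on both sides of 0. Of 81 tested arms, 41 had a fold above 0 and 40 below, with 0 called over all arms or adjusted over the list alone (median 0.02, left-out range -0.03 to 0.04, camera adjusted p = 0.945). The cluster held 9.97% ± 1.47 of normalized counts in the exercised and 9.52% ± 0.522 in the sedentary lineage. Its most abundant arms after Mir-127_3p were Mir-154-P13_5p, with 121896 ± 3942 against 112853 ± 8485 (fold 0.11), Mir-154-P7_5p with a fold of -0.08 (-0.03 without F2_sedentary replicate 3) and Mir-154-P9_3p with 0.10. At an unadjusted p below 0.05 there were 13 of its arms, 5 above 0 and 8 below. The fry test for change in either direction gave an adjusted p of 0.215. In the list of other imprinted hosts, 5 of 6 arms were below 0 with 0 called by either count (median -0.29, left-out range -0.38 to -0.18, camera adjusted p = 0.418, and 0.573 with an estimated correlation). Its members include Mir-335_3p*, from an intron of the paternally expressed Mest on chromosome 6 (30741299 to 30741396), with 1451 ± 291 against 1691 ± 320, and Mir-296_3p* with 70.4 ± 19.5 against 98.3 ± 63.7.

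The large miRNA families likewise had no called list or arm, over all arms or adjusted over the list alone. Of the let-7 family, a set of differentiation-linked miRNAs, 13 of 19 arms were below 0 (median -0.11, left-out range -0.18 to -0.07, camera adjusted p = 0.492), and the family held 8.997% ± 1.02 against 9.80% ± 0.659 of normalized counts. With 1 arm per miRNA number in each list, the let-7 family had the lowest adjusted p of the list test, 0.0555, just above the threshold. With all 19 of its arms and an estimated correlation between them (0.19), the family had a camera adjusted p of 0.939. Its 4 most abundant arms, Let-7-P12_5p, Let-7-P10_5p with its copy, Let-7-P11_5p and Let-7-P3_5p with its copy, had folds of -0.22 each, and of -0.09, -0.12, -0.07 and -0.12 without F2_exercised replicate 1. In the Mir-17 family clusters, 9 of 16 arms were above 0 (median 0.04, left-out range -0.01 to 0.20, camera adjusted p = 0.664), with Mir-92-P1a 3p at 1123 ± 253 against 1389 ± 152.8 (fold -0.33) and Mir-17-P5_5p at 0.06 (left-out range 0.01 to 0.21, the highest without F2_exercised replicate 1). In the Mir-29 family, 6 of 7 arms were above 0 (median 0.08, left-out range 0.00 to 0.14, camera adjusted p = 0.492), with Mir-29-P1a_3p at 84643 ± 6070 against 77984 ± 4595 (fold 0.12). The Mir-30 family had 4 of 11 arms above 0 (median -0.01, left-out range -0.06 to 0.08, camera adjusted p = 0.982), and the Mir-34 and Mir-449 family 2 of 6 (median -0.05, left-out range -0.26 to 0.11, camera adjusted p = 0.982). The medians of these last lists were 0.07 and 0.03 under scaling by library totals. Mir-30-P1c_5p had a fold of -0.22 and Mir-34-P1_5p of 0.31 (95% confidence interval -0.32 to 0.94). The former was -0.08 without F2_exercised replicate 1, and the latter ran from 0.15 without F2_exercised replicate 6 to 0.53 without F2_sedentary replicate 5.

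Over the whole profile, lineage accounted for 8.58% of the variance between libraries, where the mean over all ways of splitting them 6 and 6 was 9.09% (permutation p = 0.511). Libraries with a shared code stem had a mean correlation of deviations of -0.12, against -0.24 for others of the same lineage (difference 0.117, permutation p = 0.11, one-sided, over 100 arrangements). Deviations were taken from the mean of the 6 libraries of a lineage, which pulls such correlations below 0 even for independent libraries. Only the difference between them is therefore read. With the stem as a correlated unit in limma, the correlation was -0.004. Neither value shows that the libraries of a lineage are independent. Shares of passenger arms, the strand usually degraded, were 2.28% ± 0.246 and 2.14% ± 0.119 (SD, n = 6 each, exact permutation p = 0.253). The highest share, 2.72%, was in F2_exercised replicate 1.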

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

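The tests of read depth in F2_exercised replicate 1 and the counts of other splits for called and unadjusted arms were chosen after the results were seen. In 23 of the groups of 6 libraries tested, 1 library stood apart, since its gap to the nearest other library, as a ratio of the group's whole range, was above Dixon's 95% critical value. Chance would give about 10.7 such groups, 1 in 20 of those tested, if values were normally distributed and the groups separate. Arms were compared as normalized counts, and list medians stand beside their own members. The difference between 23 and 10.7 therefore does not measure an excess over chance.

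F2_exercised replicate 1 lay apart on the first principal component, at 13.5 where the other libraries lay between -7.56 and 5.09. Against the other 5 libraries of its own lineage, its Mir-124 3p value was 72090 (33004 to 46777, ratio 0.6476), Mir-191 5p 14967 (20378 to 22872, ratio 0.6844) and Mir-298_5p 402 (208.5 to 278, ratio 0.6381, but up to 407 in the sedentary lineage). Its Mir-30 family median was -0.55 (-0.07 to 0.13, ratio 0.6986) and its neurogenesis list median -0.05 (0.02 to 0.04, ratio 0.7512, but down to -0.07 in the sedentary lineage). The median of 0 of the 6 lists for cells of choroid plexus, blood, vessels or glia lay outside the range of the other libraries, but the bound set in advance on these medians was wrong and such cells stay open, since members went both ways, with 14 of 80 arms the highest and 19 the lowest of the 12 libraries. Low depth cannot be told apart from other causes, since only 1 library, F2_exercised replicate 4, had fewer reads, and it lay inside the range at -3.29. A larger share of passenger arms, which may point to a library or RNA difference, stays open: 2.72% of its counts against 2.01 to 2.34% in the others.

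Mir-451_5p had a fold of -0.65 in the exercised lineage at an unadjusted p below 0.05, with F2_sedentary replicate 2 at 550 (others of its lineage 185 to 321, ratio 0.6276). Residual blood in the tissue is a candidate explanation, and would carry Mir-144 and Mir-486 along with Mir-451. Within groups the correlation with Mir-451_5p was 0.36 and 0.38 for the Mir-144 arms and 0.08 for Mir-486_5p, a mean of 0.274 (permutation p = 0.123, one-sided). That mean lies between the bounds set in advance, so blood content and a difference between the lineages cannot be told apart here.

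In F2_sedentary replicate 5, arms of the Mir-200 and Mir-183 families and of muscle stood above the rest of its group. Mir-8-P1a_3p was 14946 (others 1304 to 3408, ratio 0.8458), Mir-8-P2a_3p 7695 (816 to 1941, ratio 0.8364), Mir-96-P3 5p 7476 (251 to 945, ratio 0.9039) and Mir-96-P2_5p 5816 (230 to 927, ratio 0.8753), with a list median of 2.86 (-0.90 to 0.49, ratio 0.6306). Mir-1 3p was 7282 (3023 to 4296, ratio 0.701) and Mir-1-P3_3p 158 (44.1 to 73.1, ratio 0.7459), with a muscle median of 0.85 (-0.32 to 0.08, ratio 0.6625), and Mir-34-P1_5p was 1391 (431.04 to 702, ratio 0.718). In F2_exercised replicate 6, Mir-133 3p was 91.8 (39.6 to 45.3, ratio 0.8901), the muscle median 0.51 (-0.16 to -0.04, ratio 0.813) and the astrocyte median 0.23 (-0.01 to 0.06, ratio 0.7137). In F2_sedentary replicate 1, Mir-338-P1_5p* was 1299 (1926 to 2243, ratio 0.6645) and Let-7-P10_5p 292176 (207635 to 238028, ratio 0.6405). In F2_sedentary replicate 2, Mir-154-P20-v1_3p was 279 (165 to 203, ratio 0.6655) and Mir-92-P2_3p 3273 (1848 to 2377, ratio 0.6288). In F2_sedentary replicate 3, Mir-296_3p* was 222 (43.8 to 105.6, ratio 0.6534).

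For the 34 arms at an unadjusted p below 0.05, chance cannot be excluded, since 23 of 100 drawn splits of the 12 libraries into 6 and 6 gave as many, the real one included, and the highest other gave 70. For the 0 called arms and the 0 called lists, a count of splits decides nothing, since every split gives at least 0 (100 of 100 for each, with 2 arms and 6 lists in the highest other). Splits that follow the code stems across lineages gave 28 (R31 and S11 against R41 and S41) and 33 arms (R31 and S41 against R41 and S11) at an unadjusted p below 0.05, with 0 called.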

How the results depend on the processing

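The choroid plexus covariate, the permutation of list medians and the fit without doubtful values of 0 were chosen after the data were seen. The number of arms called by limma was 0 under all 27 alternatives, with adjusted p from 0.318 upward. The number at an unadjusted p below 0.05, 34 as reported, was 57 under upper-quartile scaling, 16 without the S11 libraries, 19 without the S41 libraries, 43 with the choroid plexus covariate and 36 without the doubtful values of 0. Leaving out 1 library at a time gave 18 (without F2_exercised replicate 6) to 48 (without F2_sedentary replicate 4). With the mouse number as a replicate block it was 16. The labels do not say that the numbers pair the mice. Deviations of same-numbered mice correlated between -0.17 and 0.15, 1 of 6 above 0.1, and 1 of 6 matched its own number best, which cannot exclude a pairing. The cause of these shifts was not tested, beyond fewer libraries in the fits that leave some out. The number of lists called was 1 in place of 0 without the R31 (choroid plexus), R41 (endothelial and mural) or S41 libraries (choroid plexus), and 0 to 1 with 1 library left out (Mir-200 and Mir-183 without F2_sedentary replicate 5). All 4 of these calls ended with an estimated correlation. With 1 arm per miRNA number 0 lists were called, and the lowest adjusted p of the list test was 0.0555, for the let-7 family. With all arms of that family and an estimated correlation, the camera adjusted p was 0.939. Of the 84 named arms, 14 had a confidence interval that excludes 0 and all 14 kept their sign under every alternative, while 41 of the other 70 changed sign under 1 or more. The 14 were picked by their intervals in these same libraries, so their stable sign is not separate support. Upper-quartile scaling and scaling by totals moved the median of all arms from -0.00 to 0.08 and 0.09. Tests of depth, the share of the most abundant arms, stem likeness and variance stayed on their side of the threshold in every alternative run. Count models (edgeR with TMM or RLE scaling, DESeq2, voom) were not run, since the deposited values are not whole reads and their step cannot be read from the smallest value. The recovered reads would have allowed such models, so what they would call is not known. RLE scaling is already that of the deposited values. Arms below about 100 normalized counts have wide intervals: of 319 arms above that, 240 had an interval within 1.5-fold.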

Other observations

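The covariate fit, the test for different amounts of choroid plexus and that for read depth were chosen after the miRNAs had been seen to vary between libraries. MiRNAs of the choroid plexus list varied together from library to library in both lineages. Mir-1298_5p ranged from 12623 normalized counts (F2_sedentary replicate 6) to 124745 (F2_exercised replicate 3), and Mir-448_3p, from another intron of Htr2c (chromosome X, 147158210 to 147158321), from 291 to 2464 in the same libraries. With the list median as a covariate in limma, 13 arms were called for it, 12 with a positive and 1 with a negative slope, and 10 of the list's 12 arms were among them. The 3 arms outside the list, chosen after their values were seen, were Mir-95-P4_5p* (slope 1.17, adjusted p = 2.04e-05), Mir-95-P4_3p (1.16, adjusted p = 0.000223) and Mir-874_3p (-0.33, adjusted p = 0.0426). Slopes of list members are not independent of the median they enter. In that fit 0 arms were called between the lineages.

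A candidate explanation is different amounts of choroid plexus in the dissected tissue, since it lies against the hippocampus and expresses Htr2c. This stays open, since the test compared 2 parts of the same list and so shows the pattern again: within groups, mean deviations of the 5 arms hosted in Htr2c and the 7 arms from other loci correlated with Pearson r = 0.970 and Spearman rho = 0.972 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, 3e-05 adjusted over 3 relations, r = 0.951 without the 2 farthest libraries). The tables argue against read depth, with r = -0.0269 to the number of reads (rho = -0.09, permutation p = 0.935 and 0.794, r = -0.15 without the 2 farthest libraries). They did not follow the Mir-200 and Mir-183 families either (r = 0.10, rho = -0.17, permutation p = 0.830 and 0.582, r = 0.33 without the 2 farthest libraries). Regulation shared by these arms within hippocampal cells stays open too and was not tested: 7 of the 12 arms also stand in other lists, and 11 were detected in every library.

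A hypothesis on the imprinted Dlk1-Dio3 cluster was also tested, that its arms differ between the lineages in both directions. Imprinting itself was not measured. The cluster held 13 of the 34 arms at an unadjusted p below 0.05, where its share of all tested arms gives 5.81. Of the 100 splits of the libraries that were drawn, 7 gave as many cluster arms, the real one included, and the highest other split gave 22. The bound set in advance for the hypothesis was under 5, which the count misses. The opposite bound, any larger count, had been set too close to it, since a share just above a threshold does not show that the cluster stayed level, so the hypothesis stays open and chance is not excluded.

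Several arms were listed at 0 in single libraries while others held them well above 0. Mir-3085_3p was listed at 0 in F2_sedentary replicates 2 and 3 and in F2_exercised replicate 5, where the other libraries correspond to 86.5, 71.5 and 83.6 expected reads. Mir-337_3p* was listed at 0 in F2_sedentary replicate 6, against 55.7 expected reads. Both arms were chosen after their values were seen.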
